A study of Halothece sp. PCC 7418 with 6 samples.

How the data were processed

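RNA was extracted with TRIzol LS from 6 cultures of Halothece sp. PCC 7418, per the labels' protocols, and sequenced by a commercial provider. Cultures grew in BG11 medium with Turk Island salts and 0.5 M or 2.5 M NaCl under continuous light of 70 µE per square metre and second, for at least 8 days at 30 °C to an optical density of 0.6 to 0.8 at 730 nm. Each salinity has a control at 0 h, a culture 24 h after a shift to 37 °C and a culture 24 h after a shift to 23 °C. The labels give 1 library for each of these 6 groups. Whether ribosomal RNA was depleted, the library kit and its strandedness are not given in the sources used here.

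The authors deposited 1 gene table for each comparison of a shifted culture with its control, 4 in all, with gene names, products, coordinates on the chromosome and feature types. Bowtie is the aligner named in the submitters' processing notes; its version and the counting tool are not given in the sources used here. Per the file headers, the tables hold a raw read count per gene and library and an FPKM value. Per the file headers they also hold a log2 normalised value, the authors' signed fold and a p-value with its adjusted value. The authors' deposited p-values compare single libraries, rest on a spread that 1 library per group cannot estimate, and were not used to make calls. Tests on the files showed what the columns hold. Each table lists only genes with an absolute fold in the authors' deposited table of at least 2 and a p-value up to 0.0443. Adjusted values divided by p-values show that 3730 features were tested, of which 1645 are in at least 1 table. The normalised column is log2 of 1 plus CPM over a scaled library size, with deviations under 5.7e-08. The factors between scaled size and total reads were 0.9603 for the 0.5 M control, 0.7289 for 0.5 M heat, 1.113 for 0.5 M cold, 0.9317 for the 2.5 M control, 1.3228 for 2.5 M heat and 1.0413 for 2.5 M cold. Their product of 0.9999 shows that all libraries were scaled jointly, and control values are equal in both tables of a salinity. How the authors computed the factors is not given in the sources used here. The deposited annotation tables of gene ontology terms, 8 in number, were not used.

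Total reads per library were recovered from read counts, gene lengths and FPKM, and whether they hold all aligned reads or only reads in genes is not known. They were 20281846 for the 0.5 M control, 15773923 for 0.5 M heat, 20114685 for 0.5 M cold, 19062799 for the 2.5 M control, 18778075 for 2.5 M heat and 14563664 for 2.5 M cold. Normalised CPM was computed as 2 to the power of the normalised value, minus 1. The fold of a gene is the ratio of these values without a pseudocount. A gene counted as higher or lower at 2-fold with at least 10 reads in the larger library. The 95% interval of each fold is the exact interval of a ratio of Poisson rates, and reads are not independent molecules, so intervals cover counting error alone. With 1 library per group no test within a comparison was possible and none across salinities was made, no p-value was computed, and levels in genes outside the tables are not analysed here.

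Before the data were examined, 30 gene lists were fixed by patterns in gene symbols and product names. For each list with at least 5 listed genes, the median log2 fold was placed among 10000 random lists of the same size, matched on 10 expression groups and drawn from the listed genes of the same table. This percentile describes the libraries, treats genes as independent and is not a test. Genes were named by a rule also fixed beforehand. It takes, per comparison, the 6 largest folds in each direction among genes with at least 100 summed reads and an informative product name. It adds the largest fold in each direction from each list with at least 3 listed genes. It always adds listed genes for GroEL, GroES, DnaK, HtpG, ClpB, Hsp20, DEAD/DEAH box helicases, desaturases, sigma factors, glycine betaine methyltransferases and mycosporine synthesis. Genes from lists that are not discussed were left out, and genes outside the rule are marked as named after their values were seen. Overlaps were set beside the product of the list sizes over 3730 and, where a control is shared, beside 100 simulations of unchanged libraries at each of 3 spreads.

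Alternatives fixed beforehand were no read minimum, a minimum of 50 reads, thresholds of 3-fold and 4-fold, unscaled raw reads, pseudocounts of 1 and 10, a requirement that the interval exclude no change, list membership by product name alone and unmatched random lists. Scaling by total reads, scaling by total reads without those of ssrA, protein-coding genes alone, and rotations of the folds along the gene order in place of random lists, without matching on expression, were chosen after seeing the data.

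The code was tested on simulated data with 3730 genes and an assumed spread of 10% between libraries, with 200 genes changed by 2.5-fold or 4-fold. Of genes changed 2.5-fold, it recovered 87.0% for 0.5 M heat, 90.0% for 0.5 M cold, 90.0% for 2.5 M heat and 85.0% for 2.5 M cold. Of genes changed 4-fold it recovered 99.0%, 99.0%, 97.0% and 100.0% in the same order, and it called 0.708%, 0.312%, 1.22% and 0.227% of unchanged genes. Intervals were checked on separate draws with counting error alone and no spread between libraries. There they held the true fold for 95.8% of genes for 0.5 M heat and 95.9% for 0.5 M cold. The values were 95.9% for 2.5 M heat and 95.9% for 2.5 M cold. Coverage under a spread between libraries was not checked. With permuted folds, 5.0%, 3.33%, 2.5% and 4.67% of lists lay outside the central 95% in that order. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.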

Results

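Messenger RNA and other RNA of Halothece sp. PCC 7418, a halotolerant cyanobacterium, was sequenced from 6 cultures, 1 for each pairing of 2 salinities with 3 temperature conditions. Cells grew on light and carbon dioxide in medium with 0.5 M or 2.5 M NaCl at 30 °C. The control culture of each salinity was sampled at 0 h, and the others were sampled 24 h after a shift to 37 °C (heat) or 23 °C (cold). The series asks how temperature affects the transcriptome of this organism. Total reads per library ranged from 14563664 in the 2.5 M cold library to 20281846 in the 0.5 M control. There was 1 library per group, so no difference below has a replicate check and no test was made. Each fold compares 2 libraries, and the interval after it covers counting error alone. Temperature and the 24 h of further culture go together in every comparison. The authors' tables give only genes past their own thresholds of fold and p-value, so a gene that is not named in a comparison cannot be taken as equal in its libraries. Coordinates are positions on the chromosome sequence named in the files.

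The composition of the libraries differed. Shares below are of total reads inferred from FPKM, and whether that total holds all aligned reads or only reads in genes is not given in the sources used here. The transfer-messenger RNA gene ssrA (PCC7418_RS19910), whose product rescues stalled ribosomes, took 11.2% of reads in the 0.5 M control (exact binomial interval 11.1 to 11.2%) and 23.5% in the 0.5 M heat library (23.5 to 23.5%). At 2.5 M it took 6.63% of control reads (6.62 to 6.64%) and 4.39% of heat reads (4.38 to 4.40%). RNase P RNA (rnpB, PCC7418_RS19610) took 0.995% of reads in the 0.5 M control, 2.95% in 0.5 M heat, 0.548% in 0.5 M cold, 0.719% in the 2.5 M control, 0.330% in 2.5 M heat and 0.243% in 2.5 M cold. The authors' scaling moved log2 folds, relative to scaling by total reads, by 0.40 in 0.5 M heat, -0.21 in 0.5 M cold, -0.51 in 2.5 M heat and -0.16 in 2.5 M cold. Shifts of this size cannot turn the direction of a gene past 2-fold, but they alter how many genes pass that threshold.

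The first comparison asks what differed after 24 h at 37 °C in 0.5 M NaCl. A small heat shock protein gene had the largest fold among higher genes. PCC7418_RS01285 (291599 to 292066, plus strand), of the Hsp20/alpha crystallin family of ATP-independent chaperones, was 13.7-fold higher in the heat library (13.4 to 14.0), at 6527 against 475 normalised CPM (reads per scaled library size). The other 5 listed members of the chaperone and protease list were lower. They were the disaggregase gene clpB (PCC7418_RS13605; 3.63-fold, 3.47 to 3.78), Hsp20 genes PCC7418_RS07305 (2.99-fold, 2.90 to 3.09) and PCC7418_RS03770 (2.60-fold, 2.54 to 2.66), grpE at 4.01-fold and an FtsH-type protease gene (PCC7418_RS09605) at 2.23-fold. The last pair lies outside the naming rule and was named after the values were seen. The grpE fold rests on few reads, since its level was only 3.49 normalised CPM in the 0.5 M control. The list's median lay at percentile 1.34 of random lists matched on expression and drawn from the same table. It lay inside the central 95% with product names alone (2.81), unmatched random lists (3.38), total-read scaling (4.27) and rotated gene order (3.97), so this placing is weak.

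Genes of nitrogen fixation and nitrogen uptake were lower in the 0.5 M heat library. Of 16 listed genes in the nitrogen list, 13 were lower and 3 higher, with a median log2 fold of -1.48 at percentile 0.03. The gene nifE (PCC7418_RS08855), for assembly of the nitrogenase cofactor, was 8.86-fold lower (4.95 to 17.5), on 12 and 180 reads. It belongs to a run of 7 neighbouring genes, from nifU (PCC7418_RS08830; 6.62-fold lower, 5.86 to 7.50) to nifN, at 1951029 to 1959449, that were all lower. The substrate-binding gene of molybdate uptake, modA (PCC7418_RS08910; 1964097 to 1964930), was 14.7-fold lower (9.29 to 24.6). The urea transporter genes urtB, urtC, urtD and urtE, named after their values were seen, were 2.76 to 4.39-fold lower. Among the 3 higher members was a gene for a P-II nitrogen regulator (PCC7418_RS00670; 2.63-fold, 2.59 to 2.67). The iron and metal list also lay low, at percentile 0.205, but its 5 lower members were nif genes that the nitrogen list already holds. In cold the nitrogen list was mostly lower too, 11 of 15 genes at 0.5 M (percentile 26.9) and 9 of 10 at 2.5 M (percentile 50.1). The gene nifE was 6.47-fold lower (4.42 to 9.74) in 0.5 M cold. The direction is therefore not particular to heat, and heat and cold at 0.5 M share their control library.

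Phosphate uptake genes went the other way. All 6 listed genes of the phosphate and sulfate list were higher in 0.5 M heat, with a median log2 fold of 1.74 at percentile 99.7. An alkaline phosphatase gene (PCC7418_RS17240; 3774756 to 3778145) was 6.31-fold higher (5.81 to 6.87), and the others were genes of phosphate ABC transporters. With a minimum of 50 reads the list lay at percentile 93.9, inside the central 95%, and with total-read scaling only 3 of its genes stayed past 2-fold. All 12 listed ribosomal protein genes were higher, at percentile 96.6, with rpmG (PCC7418_RS19690) at 2.77-fold (2.47 to 3.11). Their median log2 fold was 1.30, of which 0.40 comes from the authors' scaling, so with total-read scaling some fall under 2-fold. Of 22 listed transposase genes, 21 were higher, at percentile 97.3. The transposase accessory gene tnpB PCC7418_RS08115 was 4.92-fold higher (4.49 to 5.39). Transposase genes can occur in near-identical copies, which was not checked here, and reads shared among copies would make their values uncertain.

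Carbon metabolism and photosynthesis held single genes with large folds at 0.5 M heat. Neighbouring genes for a phosphoketolase (PCC7418_RS14175) and a glycogen phosphorylase (PCC7418_RS14170), at 3107473 to 3112505, were 7.66-fold (6.66 to 8.85) and 6.12-fold (5.13 to 7.37) lower. The psbA copy PCC7418_RS14700, for the D1 protein of photosystem II, was 5.25-fold lower (5.14 to 5.36), while psbU (PCC7418_RS00740) was 2.57-fold higher (2.52 to 2.62). Several psbA copies are annotated; their sequences were not compared here, and the split of reads among them is uncertain if they are near-identical. A short gene annotated as a chlorophyll a/b binding protein (PCC7418_RS18290) was 5.75-fold lower (5.55 to 5.96). Genes for a superoxide dismutase (PCC7418_RS12725; 3.80-fold, 3.73 to 3.87), ATP synthase subunit I (PCC7418_RS02120; 4.06-fold, 4.01 to 4.12) and an RNA-binding protein (PCC7418_RS12005; 7.84-fold, 6.72 to 9.18) were higher. A thioredoxin fold gene (PCC7418_RS01415; 4.89-fold, 4.36 to 5.50), an ATP synthase delta gene (PCC7418_RS12435; 3.64-fold, 2.35 to 5.86) and a DEAD/DEAH box helicase gene (PCC7418_RS07075; 3.01-fold, 1.51 to 6.65) were lower. A sigma-70 family sigma factor gene (PCC7418_RS00080) was 2.89-fold lower (2.01 to 4.25). The ATP synthase list had 2 higher and 3 lower genes and the oxidative stress list 2 and 2. Also higher was the sedoheptulose 7-phosphate cyclase gene PCC7418_RS07910 (2.52-fold, 2.23 to 2.85), whose enzyme family begins the synthesis of mycosporine-like sunscreen compounds.

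All 35 listed features that do not encode proteins were higher in the 0.5 M heat library, by 2.12 to 12.9-fold, while 222 protein-coding genes were higher and 298 lower. They comprised 28 transfer RNAs, 3 5S ribosomal RNAs, ssrA, rnpB, the signal recognition particle RNA and a further non-coding RNA. Genes for tRNA-Ser (PCC7418_RS09010; 11.7-fold, 9.66 to 14.4) and tRNA-Leu (PCC7418_RS18350; 11.1-fold, 7.66 to 16.5) had the largest folds among those with at least 100 summed reads. The 3 5S ribosomal RNA genes had only 65, 25 and 211 reads in 0.5 M heat and 22, 12 and 94 in the control. In 0.5 M cold, non-coding features were mostly higher as well, 15 of 17, with 12 of 13 transfer RNAs and 3 of 3 ribosomal RNAs (4.71 to 7.08-fold). With so few control reads, folds of ribosomal RNA genes are not read as changes in the amount of ribosomal RNA.

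In all, 257 genes were at least 2-fold higher and 298 at least 2-fold lower in 0.5 M heat, together 14.9% of the 3730 features tested. The share that was higher is 46.3% with the authors' scaling. With total-read scaling, chosen after seeing the data, it is 24.9%, from 99 higher and 298 lower genes. Here and in the other comparisons this scaling could only remove listed genes. Genes that it would bring past 2-fold are missing, so these are not the shares among all genes. Lists outside the central 95% of random lists numbered 4 of 12. Neighbouring genes mostly share a direction, so lists of neighbours could fall outside more often than lists of independent genes. Against rotations of the folds along the gene order, which keep neighbours together but drop the matching on expression, 5 lists lay outside. They were nitrogen (0.812), iron and metal (0.451), phosphate and sulfate (99.8), ribosomal proteins (98.2) and transposases (99.8).

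**Figure D1:**
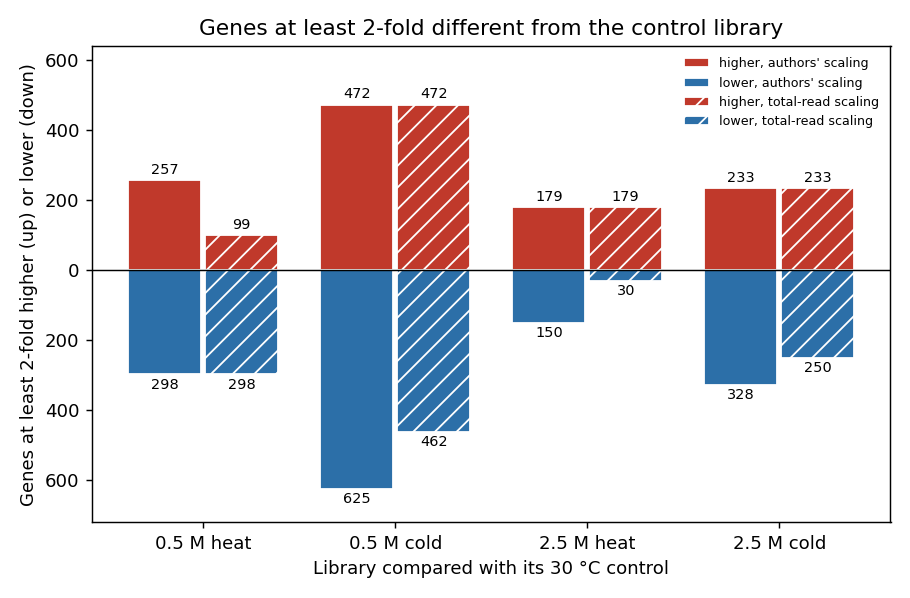
Number of genes at least 2-fold higher (red, upward) or lower (blue, downward) in each shifted library than in the 30 °C control library of the same salinity, 1 library per group. Plain bars use the authors' scaling and hatched bars total reads per library. In 0.5 M heat the count of higher genes is 257 with the first and 99 with the second. Hatched bars count only genes already past 2-fold with the authors' scaling.

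The second comparison asks what differed after 24 h at 23 °C in 0.5 M NaCl. Listed ribosomal protein genes were higher, and listed genes of the photosystems and the phycobilisome lower. All 42 listed ribosomal protein genes were higher in the cold library, with a median log2 fold of 1.90 that exceeded every random list (percentile 100). The gene rpsB (PCC7418_RS02415; 534372 to 535196), for protein S2 of the small subunit, was 7.18-fold higher (6.86 to 7.51). The GTPase gene typA (PCC7418_RS06020; 1323162 to 1324955), whose product acts on the ribosome, was 10-fold higher (9.57 to 10.5). All 7 listed tRNA synthetase genes were higher too, led by the beta subunit for phenylalanine (PCC7418_RS02205; 2.70-fold, 2.59 to 2.81), at percentile 82.7.

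All 11 listed photosystem I genes were lower in 0.5 M cold (percentile 0.275), as were all 11 photosystem II genes (percentile 1.78) and all 9 phycobilisome genes (percentile 1.12). Against rotated gene order only the photosystem I list stayed outside the central 95% (0.456), with photosystem II at 8.39 and the phycobilisome at 5.84. The photosystem I subunit IX gene PCC7418_RS05705 was 12.5-fold lower (10.9 to 14.4). A phycobilisome linker gene (PCC7418_RS15845; 3453318 to 3454178), for a protein that holds the antenna rods together, was 8.24-fold lower (8.11 to 8.36), at 833 against 6859 normalised CPM. The psbA copy PCC7418_RS13355 was 5.88-fold lower (5.84 to 5.92). Subunit B of the light-independent protochlorophyllide reductase (PCC7418_RS01410), an enzyme of chlorophyll synthesis, was 9.27-fold lower (8.88 to 9.68). The hydrogenase and fermentation list lay at percentile 0.985 with 8 of 11 genes lower, among them hoxU (PCC7418_RS14985; 9.22-fold, 8.34 to 10.2).

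Membrane lipid and cold-associated genes were higher on balance in 0.5 M cold. Of 10 listed genes in the desaturase and lipid list, 9 were higher (percentile 98.6). A fatty acid desaturase gene (PCC7418_RS16810; 3667700 to 3668764), of the enzymes that add double bonds to membrane lipids, was 9.62-fold higher (8.97 to 10.3). This list also holds the carotenoid desaturase genes zds and pds, which were 3.59-fold and 3.77-fold higher and were named after their values were seen. In the cold response and RNA list, 5 of 7 genes were higher (percentile 97.9), including the RNA-degrading polynucleotide phosphorylase gene PCC7418_RS04590 (3.71-fold, 3.61 to 3.81) and the DEAD/DEAH box helicase gene PCC7418_RS10835 (2.86-fold, 2.56 to 3.19). A second helicase gene, PCC7418_RS07075, was 2.93-fold lower (1.72 to 5.19), and a cold shock domain gene (PCC7418_RS03035) was 2.21-fold lower (2.0 to 2.45). The cold response list lay inside the central 95% with product names alone (96.3), a minimum of 50 reads (97.2) and total-read scaling (94.8), and the desaturase list with total-read scaling (97.0).

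Chaperone genes were divided at 0.5 M cold, with 8 higher and 7 lower. Higher were groES (PCC7418_RS06735; 2.27-fold, 2.20 to 2.33), groL PCC7418_RS06740 (2.55-fold, 2.53 to 2.58), groL PCC7418_RS07440 (2.01-fold, 1.99 to 2.03), dnaK (PCC7418_RS13095; 2.55-fold, 2.39 to 2.73) and the trigger factor gene (PCC7418_RS16670; 4.18-fold, 3.98 to 4.38). The 3 Hsp20 genes PCC7418_RS01285, PCC7418_RS03770 and PCC7418_RS07305 were 2.51-fold (2.42 to 2.61), 2.44-fold (2.40 to 2.48) and 3.22-fold (3.14 to 3.31) lower. The gene htpG (PCC7418_RS12345) was 2.06-fold lower (2.0 to 2.12). The gene grpE (PCC7418_RS02600), whose product works with DnaK, was 4.6-fold lower on 85 summed reads and was named after its value was seen.

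ATP synthase genes lie in separate clusters that differed in direction in 0.5 M cold. The 8 listed genes from PCC7418_RS02120 to PCC7418_RS02155 were 2.18 to 3.34-fold higher. The 6 listed genes between PCC7418_RS12435 and PCC7418_RS12465 were 3.70 to 7.62-fold lower. Levels also differed, since subunit A had 1823 normalised CPM in the control in the first cluster (PCC7418_RS02125) and 19.0 in the second (PCC7418_RS12445). Phosphate and sulfate genes were mostly higher, 7 of 9 (percentile 98.1, but 96.0 and inside the central 95% against rotated gene order), with the phosphate-binding gene PCC7418_RS16135 at 5.10-fold (4.75 to 5.49). All 25 listed toxin-antitoxin and CRISPR genes were lower (percentile 8.27), led by the CRISPR-associated gene PCC7418_RS03435 (759923 to 761071; 30.2-fold, 26.1 to 35.2) and csx10 (PCC7418_RS03425; 23.6-fold, 19.9 to 28.3). Of 16 transposase genes 14 were lower.

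Other large folds in 0.5 M cold were those of an ABC transporter gene (PCC7418_RS13185; 18.0-fold higher, 15.9 to 20.4), the pantoate ligase and CMP kinase gene PCC7418_RS00875 (9.82-fold higher, 9.19 to 10.5) and the chemotaxis gene for CheW (PCC7418_RS05030; 19.5-fold lower, 16.5 to 23.1). A hemerythrin-family gene (PCC7418_RS11385) was 19.3-fold lower (15.4 to 24.7) in cold and 6.60-fold lower (5.45 to 8.05) in heat at this salinity. A sigma-70 family sigma factor gene (PCC7418_RS06885) was 2.30-fold higher (2.02 to 2.62) in 0.5 M cold. In all, 472 genes were at least 2-fold higher and 625 lower, 29.4% of features tested. The share that was higher is 43.0%, and 50.5% among listed genes that stay past 2-fold with total-read scaling. Lists outside the central 95% of random lists numbered 8 of 21, and 5 against rotated gene order.

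**Figure D2:**
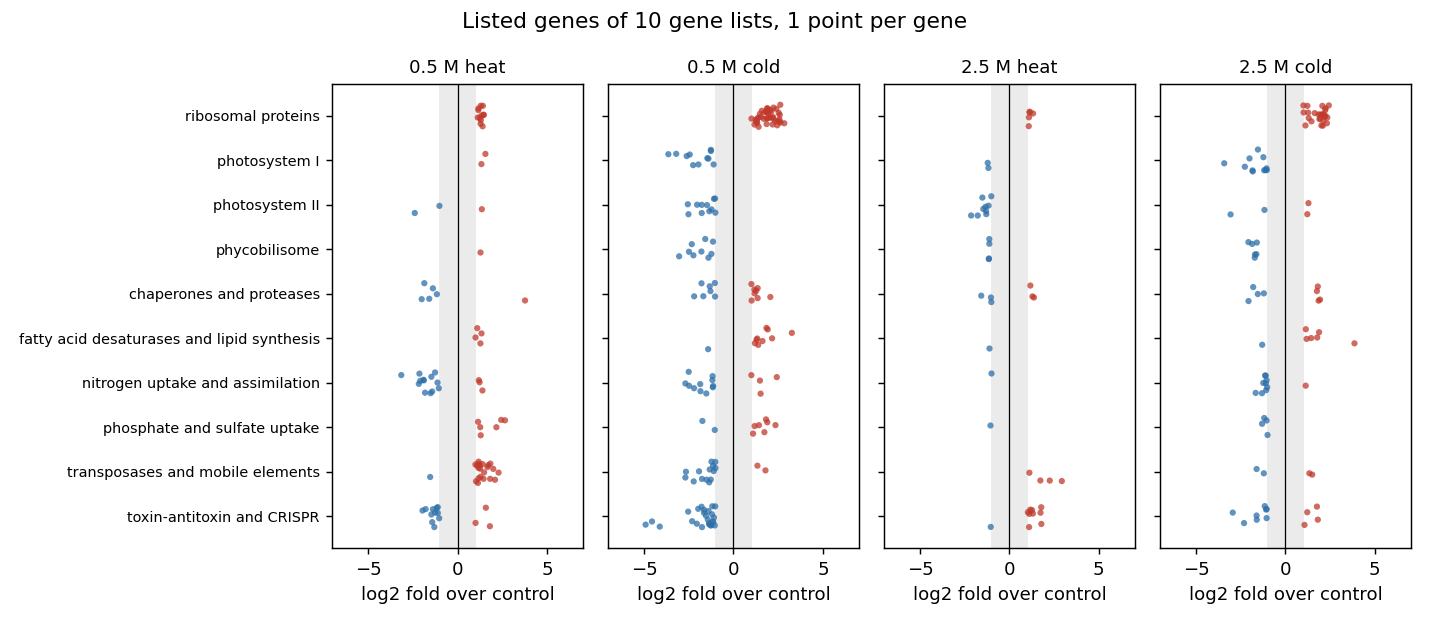
Log2 fold over the 30 °C control for listed genes of 10 gene lists in the 4 comparisons, 1 point per gene with small vertical jitter, red for higher and blue for lower. The grey band marks folds under 2, which the tables do not hold; all 42 ribosomal protein points at 0.5 M cold lie to its right and all 11 photosystem I points to its left.

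The third comparison asks what differed after 24 h at 37 °C in 2.5 M NaCl, and it held the fewest genes. Listed photosynthesis genes were lower throughout, though most of their lists did not stand out from random ones. All 9 listed photosystem II genes were lower (percentile 7.67), as were all 4 phycobilisome genes, both photosystem I genes and all 6 genes of the electron carrier list (percentile 9.35). The psbA copy PCC7418_RS14700 was 4.42-fold lower (4.38 to 4.46), apcB (PCC7418_RS04780), for a core antenna protein, 2.23-fold (2.14 to 2.31) and psaC (PCC7418_RS18595) 2.32-fold (2.29 to 2.36). A gene annotated as a chlorophyll a/b binding light-harvesting protein (PCC7418_RS17760; 3882830 to 3884326) was 8.60-fold lower (5.96 to 12.7), and PCC7418_RS18290 was 6.63-fold lower (6.45 to 6.81). The functions behind these product names were not checked. In the list of chlorophyll, heme and carotenoid synthesis, 7 of 9 listed genes were lower (percentile 1.22). Its name patterns also take in chlorophyll-binding protein genes, PCC7418_RS17760 and PCC7418_RS18290 among them. It is therefore not a list of synthesis genes alone, and its placing without them was not computed. With total-read scaling only 30 of the 150 lower genes of this comparison stay at least 2-fold lower.

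The small heat shock gene PCC7418_RS01285 was 2.59-fold higher (2.54 to 2.63) in 2.5 M heat, and 3 genes of its list were higher and 3 lower. An FtsH-type protease gene (PCC7418_RS17660) was 2.99-fold lower (2.95 to 3.02). All 5 listed ribosomal protein genes, which lie in 1 stretch of the chromosome, were higher (percentile 77.4), with rpsS (PCC7418_RS15500) at 2.49-fold (2.25 to 2.77). Toxin-antitoxin and CRISPR genes were higher in 9 of 10 cases (percentile 44.8), with the RelE/ParE-type toxin gene PCC7418_RS11135 at 3.45-fold (2.28 to 5.38). The largest fold among named higher genes was that of an MgtC-family gene (PCC7418_RS12470; 6.97-fold higher, 4.39 to 11.7), on 195 and 20 reads. The transposase accessory gene tnpB PCC7418_RS04145 was 4.78-fold higher (4.54 to 5.03). An iron uptake porin gene (PCC7418_RS18695) was 2.40-fold higher (2.26 to 2.54).

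In all, 179 genes were at least 2-fold higher and 150 lower in 2.5 M heat, 8.82% of features tested. The share that was higher is 54.4% with the authors' scaling. Among listed genes that stay past 2-fold with total-read scaling, 179 higher and 30 lower, it is 85.6%. Of 16 non-coding features, 12 were higher and 4 lower, and ssrA was 2.14-fold and rnpB 3.09-fold lower. Only 1 of 8 gene lists lay outside the central 95%, that of chlorophyll, heme and carotenoid synthesis with its chlorophyll-binding members. With total-read scaling it lay inside (6.93). Against rotated gene order 2 lists lay outside, this list (0.915) and photosystem II (0.610).

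The fourth comparison asks what differed after 24 h at 23 °C in 2.5 M NaCl. Ribosomal protein genes were again higher, all 25 listed (median log2 fold 2.01, percentile 100). The gene for protein L24 (PCC7418_RS15535; 3394646 to 3394957) was 5.38-fold higher (4.95 to 5.86), and infA (PCC7418_RS15580), for translation initiation factor 1, 2.77-fold (2.58 to 2.96). The gene for initiation factor 3 (PCC7418_RS16380) was 2.85-fold lower (2.65 to 3.07). Of the 25, 18 form an unbroken run of same-strand neighbours at 3389265 to 3397987 that was higher in both cold libraries. At 0.5 M the run extended over 29 genes to 3404642. All 11 listed photosystem I genes (percentile 2.21) and all 6 phycobilisome genes (percentile 1.77) were lower. Both lists lay inside the central 95% with unmatched random lists (6.0 and 6.27) and rotated gene order (6.79 and 7.86). Of 4 listed photosystem II genes, 2 were higher and 2 lower. The gene psaK (PCC7418_RS07560) was 10.7-fold lower (9.64 to 12) and the linker gene PCC7418_RS15845 was 4.20-fold lower (4.15 to 4.26).

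**Figure D3:**
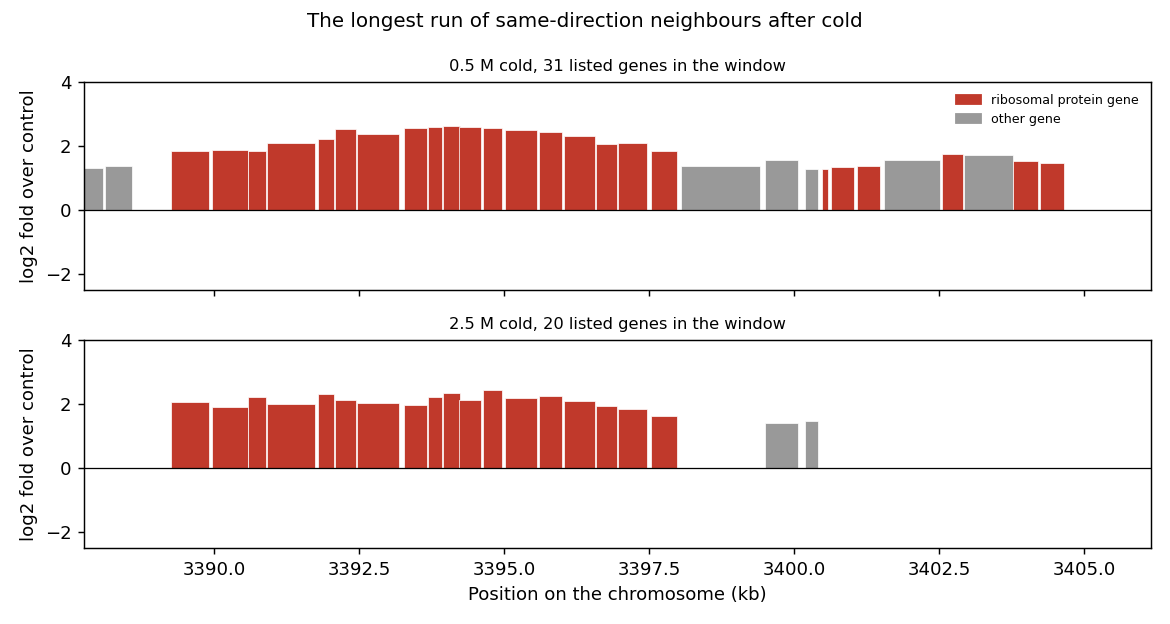
Log2 fold over control against chromosomal position in kilobases for the listed genes around the longest run of same-direction neighbours, in 0.5 M cold (top) and 2.5 M cold (bottom). Each bar spans 1 gene, red for ribosomal protein genes and grey for others; the run holds 29 genes at 0.5 M and 18 at 2.5 M, all higher.

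Pigment and photoprotection genes carried some of the largest folds in 2.5 M cold. An orange carotenoid-binding protein gene (PCC7418_RS09925; 2200029 to 2200988), of the proteins that quench excess energy in the phycobilisome, was 16.7-fold lower (15.7 to 17.9). Another short gene so annotated (PCC7418_RS15755; 3435481 to 3435972) was 4.82-fold higher (4.72 to 4.92). The neighbouring gene, for a protein of the nuclear transport factor 2 family (PCC7418_RS15760; 3436218 to 3436628), was 31.9-fold higher (26.8 to 38.3). Protochlorophyllide reductase subunit B (PCC7418_RS01410) was 13.2-fold lower (12.4 to 14.1). In the list of chlorophyll, heme and carotenoid synthesis, which also holds chlorophyll-binding protein genes, 15 genes were lower and 8 higher (percentile 4.38). Among psbA copies, PCC7418_RS03535 was 8.39-fold lower (7.42 to 9.53) and PCC7418_RS14700 was 2.44-fold higher (2.43 to 2.46).

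The fatty acid desaturase gene PCC7418_RS16810 was 14.6-fold higher (13.4 to 15.9) in 2.5 M cold, and the acyl-CoA desaturase gene PCC7418_RS06165 was 2.27-fold higher (2.15 to 2.40). Their list had 6 higher and 1 lower gene (percentile 89.2). The genes groES (PCC7418_RS06735; 3.39-fold, 3.22 to 3.57), groL PCC7418_RS06740 (3.62-fold, 3.56 to 3.69) and groL PCC7418_RS07440 (3.83-fold, 3.76 to 3.89) were higher, and Hsp20 gene PCC7418_RS01285 was 3.49-fold lower (3.37 to 3.62). The ATP synthase genes were divided by cluster as at 0.5 M, with 7 higher in the first cluster and 5 lower in the second. The sedoheptulose 7-phosphate cyclase gene PCC7418_RS07910 was 3.11-fold higher (2.93 to 3.31). All 4 listed phosphate and sulfate genes were lower. They were cysK (PCC7418_RS08775; 2.48-fold, 2.24 to 2.74), the alkaline phosphatase gene PCC7418_RS17240 at 2.0-fold, pstS at 2.28-fold and pstC at 2.08-fold, the last 3 named after their values were seen. Of these, cysK and pstS were lower in 0.5 M cold too (3.34-fold and 2.07-fold), and the alkaline phosphatase gene was higher there.

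Chemotaxis genes had the largest folds of 2.5 M cold. The gene for CheW (PCC7418_RS05030) was 55.7-fold lower (44.0 to 71.5), on 70 and 4564 reads, and its neighbour for a methyl-accepting chemotaxis protein (PCC7418_RS05025) was 40.9-fold lower (36.2 to 46.5). The phosphoenolpyruvate synthase gene ppsA (PCC7418_RS07395; 1632941 to 1635376), for an enzyme that makes phosphoenolpyruvate from pyruvate, was 36.7-fold lower (33.2 to 40.7). A DoxX-family gene (PCC7418_RS18670) was 14.4-fold higher (13.6 to 15.2) in 2.5 M cold and 3.65-fold lower (3.31 to 4.02) in 2.5 M heat. In all, 233 genes were at least 2-fold higher and 328 lower, 15.0% of features tested. The share that was higher is 41.5%, and 48.2% among listed genes that stay past 2-fold with total-read scaling. Lists outside the central 95% numbered 3 of 15, and against rotated gene order only the ribosomal protein list did (99.3).

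The cold comparisons of the 2 salinities, which share no library, can be set side by side. They had 371 genes in common, of which 152 were higher at both salinities, 212 lower at both and 7 opposed. Same-direction genes made up 98.1% (exact binomial interval 96.2 to 99.2%), and independent lists of these sizes would give 84.4 same-direction genes and 80.5 opposed ones. The desaturase gene PCC7418_RS16810, groES, the groL genes, the ribosomal run and the ABC transporter gene PCC7418_RS13185 were among those higher in both. The heat comparisons had 82 genes in common, with 32 higher at both salinities, 25 lower at both and 25 opposed. Same-direction genes made up 69.5% (58.4 to 79.2%), or 57 where independent lists would give 24.3. The 25 opposed genes are about what independent lists would give (24.6). The intervals of both shares treat genes as independent, though neighbours mostly share a direction, so they are likely too narrow. They also cover no variation between cultures. The Hsp20 gene PCC7418_RS01285 was higher in both, and psbA PCC7418_RS14700 and PCC7418_RS18290 were lower in both.

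**Figure D4:**
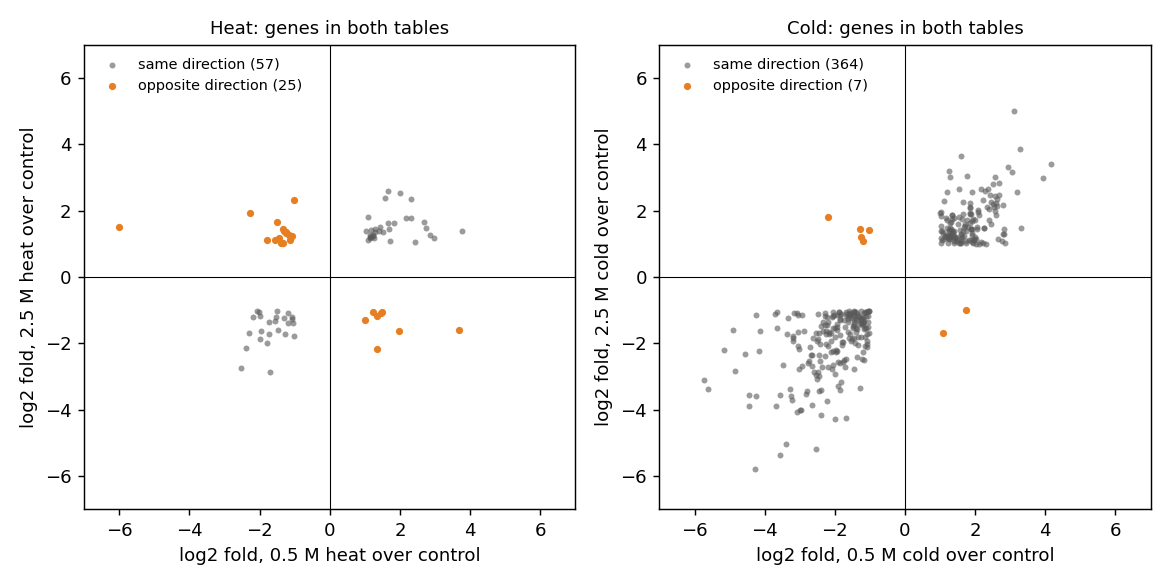
Log2 fold over control at 0.5 M NaCl (horizontal) and 2.5 M NaCl (vertical) for genes in both heat tables (left) and both cold tables (right), 1 point per gene. Orange points are genes with opposite directions, 25 of 82 for heat and 7 of 371 for cold.

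Heat and cold of one salinity share their control library, so part of their overlap may be chance in that library. At 0.5 M, 276 genes were in both lists, 245 in the same direction (88.8%), where independent lists would give 82.5. At 2.5 M, 105 were in both, 87 in the same direction (82.9%), where independent lists would give 24.4. Simulated unchanged libraries against the same control put 2.19 genes in both lists at 0.5 M if libraries vary by 10% around their mean, 16.3 at 20% and 332.5 at 40%. The matching values at 2.5 M were 5.75, 23.3 and 335.8, and at least 96.3% of such genes had the same direction. The spread between cultures is unknown here and the single control library could not be split, so the excess over either value is not read as a shared effect. The Hsp20 gene PCC7418_RS01285 was higher in heat and lower in cold at both salinities. The short gene PCC7418_RS18290 did the reverse, at 3.79-fold higher (3.75 to 3.84) in 0.5 M cold.

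The 2 control libraries were scaled together by the authors, so salinity at 30 °C can be described for the 513 genes with a value in both. These genes were selected for temperature, not salinity. The 2.5 M control was at least 2-fold higher for 68, at least 2-fold lower for 155 and within 2-fold for 290, with a median log2 ratio of -0.32. Rescaling raw reads by the median ratio gave 107 higher and 129 lower. At 2-fold with the authors' scaling, 4 of 8 chaperone and protease genes and 8 of 11 toxin-antitoxin and CRISPR genes were lower at 2.5 M. So were 4 of 5 transposase genes and 7 of 12 iron and metal genes. Higher were 0, 0, 0 and 1 in the same order. The hydrogenase and fermentation list had 3 of 8 genes higher and 1 lower. No rule fixed beforehand chose these lists. No gene of the glycine betaine or gas vesicle lists is analysed here.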

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

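The tests of the authors' scaling and of counting noise in this part were chosen after the results were seen. So was the reading of the short RNA test given below. Exact binomial intervals in this part treat genes as independent and cover no variation between cultures.

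Between the heat comparisons of the salinities, 25 genes had opposite directions, and between the cold comparisons 7 did. Independent lists of these sizes would give 24.6 and 80.5, so the number opposed in heat is about what unrelated lists would hold and is not itself a departure. These differences were not tested, since each rests on single libraries. Among the opposed genes in heat was RNase P RNA (rnpB), 3.90-fold higher at 0.5 M and 3.09-fold lower at 2.5 M, a log2 difference of 3.59. The tmRNA gene ssrA was 2.78-fold higher at 0.5 M and 2.14-fold lower at 2.5 M, a log2 difference of 2.57. As a share of total reads it went from 6.63% to 4.39% at 2.5 M, which is less than 2-fold. A tRNA-Pro gene (PCC7418_RS10295) was 2.57-fold higher and 4.51-fold lower, with a log2 difference of 3.53. A mechanosensitive ion channel gene (PCC7418_RS14200), of the channels that open under membrane tension, was 4.79-fold lower at 0.5 M and 3.76-fold higher at 2.5 M, a log2 difference of -4.17. A HicB antitoxin gene (PCC7418_RS18470) was 3.45-fold lower and 2.15-fold higher, a log2 difference of -2.89, on only 45 and 15 reads at 2.5 M. In cold, the alkaline phosphatase gene PCC7418_RS17240 was 3.32-fold higher at 0.5 M and 2.0-fold lower at 2.5 M, a log2 difference of 2.73. The genes rnpB and ssrA lie outside the naming rule and were named after their values were seen.

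The authors' scaling of the heat libraries shifts all genes of a library alike, so it would oppose genes 1 way round. Of the opposed genes in heat, 17 were lower at 0.5 M and higher at 2.5 M and 8 the other way round, which argues against scaling as the whole cause; a first test, whether they stay opposed under total-read scaling, was dropped after it was run because no gene past 2-fold can change direction under it. A difference between the 2 control libraries also falls short as the whole cause. The heat libraries differed less than the controls in 48% of the opposed genes (exact binomial interval 27.8 to 68.7%), below the 75% set beforehand. The share was similar among same-direction genes, 23 of 57 (40.4%). Over the opposed genes the median absolute log2 difference was 1.51 between controls and 1.54 between heat libraries. A part played by the controls therefore stays open. Counting noise in genes with few reads is argued against as the whole cause, since 15 of the 25 have counting intervals, corrected for all features tested, that exclude no change in both comparisons; it stays open for the other 10, and the test set beforehand, the opposed share of 20% (7.71 to 38.6%) among 30 shared genes with at least 1000 summed reads in each comparison, decided nothing. Variation between cultures and a response to heat that depends on salinity cannot be tested with single libraries.

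The 0.5 M heat library had all 35 listed non-coding features higher, and the authors' scaling of this library does not account for that alone, since 27 of the 35 (77.1%, exact binomial interval 59.9 to 89.6%) remained at least 2-fold higher with total-read scaling. More short RNA kept in this library, at extraction or library preparation, stays open. Among listed protein-coding genes the share that was higher differed by -2.51 percentage points between genes of at most 300 bp and longer ones (interval -14.6 to 9.58), which met the bound written beforehand for excluding that explanation, below 20 points, and was first read so. The reading was changed to open after the value was seen, because 96.6% of neighbouring coding genes went the same way, so that genes appear to be transcribed together and gene length says little about RNA length. In 0.5 M cold 15 of 17 listed non-coding features were higher too, so the direction is not particular to the heat library. Both comparisons share the 0.5 M control library, so part of this agreement may be chance in that library. At 2.5 M, with another control, 12 of 16 were higher in heat, with ssrA and rnpB lower, and 1 of 3 in cold. An effect of heat on these RNAs was not tested.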

How the results depend on the processing

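No paired analysis was possible within a comparison because each group holds 1 library; pairing by salinity, with 2 pairs for each shift and only genes selected in both tables, was not done. The protein-coding restriction, the total-read scalings with and without the tmRNA, and their values were chosen after seeing the data. No read minimum and the interval requirement could change no count of higher or lower genes. All listed genes already had at least 10 reads in the larger library and intervals that exclude no change. A minimum of 50 reads, a pseudocount of 1 and protein-coding genes alone kept every such count within 1.5 times. Stricter thresholds lower the counts by construction. At 3-fold, higher and lower genes numbered 65 and 83 in 0.5 M heat, 165 and 285 in 0.5 M cold, 40 and 26 in 2.5 M heat, and 89 and 149 in 2.5 M cold. At 4-fold they numbered 38 and 36, 80 and 164, 16 and 8, and 46 and 91. A pseudocount of 10, which shrinks the folds of genes with few reads, gave 141 and 111, 313 and 305, 24 and 87, and 148 and 179. Unscaled raw reads gave 52 higher genes in 0.5 M heat, 34 lower in 2.5 M heat and 151 higher in 2.5 M cold. Total-read scaling gave 99 higher in 0.5 M heat and 30 lower in 2.5 M heat, and leaving the tmRNA out of the totals gave 168 and 36. These scaling counts cover only genes already in the tables, so genes that another scaling would bring past 2-fold are missing from them, and the cause was not tested. Gene lists outside the central 95% numbered 3 in 2.5 M heat and 1 in 2.5 M cold with unmatched random lists, and 0 in 2.5 M heat with total-read scaling, against 1, 3 and 1; the cause was not tested. With rotated gene order, added after seeing the data, they numbered 5 in 0.5 M cold against 8, 2 in 2.5 M heat against 1 and 1 in 2.5 M cold against 3; rotation keeps neighbours together and drops the matching on expression, and which of these moved the counts was not tested. At 3-fold, genes shared in the same direction numbered 41 (97.6%) for heat and cold at 0.5 M, 13 for heat and cold at 2.5 M, 16 (84.2%) for heat across salinities and 150 (99.3%) for cold across salinities. With raw reads rescaled by the median ratio, 107 genes were higher in the 2.5 M control, against 68; the cause was not tested. In 2.5 M heat the share of higher genes in the iron and metal list went from 42.9% to 100% with total-read scaling, and in the signalling list from 42.9% to 60%, because lower genes dropped under 2-fold. Of 362 list shares under alternatives, 354 stayed within the exact binomial interval of the main share. Another 6 left it on the same side of an even split, and 2, those just given, crossed it. No read minimum and unmatched random lists cannot alter a share, and the intervals of short lists are wide. The 354 therefore say little about robustness. Of 170 log2 folds of named genes, 155 stayed at least 2-fold under unscaled reads, 168 and 140 under pseudocounts of 1 and 10, and 161 under total-read scaling, settings too small to turn a direction. Depth limits genes with few reads, since 69, 67, 41 and 54 listed genes in the order above had under 100 summed reads.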

Other observations

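The genes in this paragraph were chosen after their values were seen. A chemotaxis cluster at 1090680 to 1094439 held the most extreme pair of 2.5 M cold, and its response regulator (PCC7418_RS05035) was lower in all 4 comparisons, by 2.28-fold in 0.5 M heat, 9.45-fold in 0.5 M cold, 2.62-fold in 2.5 M heat and 12.1-fold in 2.5 M cold. A CRISPR type III cluster from cas10 (PCC7418_RS03415) to PCC7418_RS03440 was lower in both cold libraries, with csx10 (PCC7418_RS03425) 23.6-fold lower at 0.5 M and 4.98-fold lower at 2.5 M. Genes for pigment enzymes also lay together. The neighbouring genes acsF (PCC7418_RS08460), a heme oxygenase gene (PCC7418_RS08465) and hemN (PCC7418_RS08470) were 5.51-fold, 6.71-fold and 6.29-fold lower in 0.5 M cold and 7.86-fold, 5.76-fold and 5.08-fold lower in 2.5 M cold. The flavodoxin gene fldA (PCC7418_RS17755), whose product can replace ferredoxin, was 6.83-fold lower in 2.5 M cold, on 4 and 32 reads. The gene next to it, annotated as light-harvesting (PCC7418_RS17760), was 9.39-fold lower there.

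Of 26 genes in all 4 tables, 13 were lower in all 4 comparisons, 1 was higher in all 4 and 12 were mixed. Heat and cold of a salinity share their control library, so part of this agreement may be chance in the controls. The 13 include 2 neighbouring flotillin genes (PCC7418_RS02310 and PCC7418_RS02315), a sigma 54-interacting regulator gene (PCC7418_RS10175; 14.9-fold lower in 2.5 M cold), ruvA (PCC7418_RS01405), the protochlorophyllide reductase gene next to it (PCC7418_RS01410) and urtB (PCC7418_RS07285). The gene higher in all 4 encodes a tRNA-Ala (PCC7418_RS10815). Listed neighbours on the same strand within 200 bp went the same way in 91 of 94 pairs in 0.5 M heat, 358 of 375 in 0.5 M cold, 48 of 49 in 2.5 M heat and 160 of 163 in 2.5 M cold, where independent directions would give 50.3% to 51.4% of pairs.

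All tests in this paragraph were chosen after the results were seen. Ribosomal protein genes were higher and photosystem I and phycobilisome genes lower in both cold libraries, and a shift of expression from light harvesting to translation in the cold is a hypothesis that replicate cultures with 24 h controls at 30 °C would have to test; against rotated gene order the phycobilisome list lay inside the central 95% at both salinities (5.84 and 7.86) and the photosystem I list at 2.5 M (6.79). A bias by gene length is argued against, since at most 37.7% of other listed coding genes up to 600 bp were higher in either cold table. Neighbours mostly went the same way here too, so gene length says little about RNA length and a bias by RNA length stays open. A single transcription unit is argued against as the source of all of them, since the listed ribosomal protein genes lay in at least 5 separate stretches of the chromosome in either table. At 2.5 M, though, 18 of the 25 form 1 run, which weighs heavily in the median of that list. An effect of 24 h of culture common to both temperature shifts cannot be told apart from cold, because the only controls were taken at 0 h. Of the listed photosystem I and phycobilisome genes in the heat tables, 3 of 3 were higher at 0.5 M and 0 of 6 at 2.5 M. Median log2 folds of the 2 lists were 1.45 and 1.28 at 0.5 M and -1.20 and -1.14 at 2.5 M. The authors' scaling moved folds by 0.40 at 0.5 M and -0.51 at 2.5 M. With total-read scaling most of these genes keep their direction but fall under 2-fold, so the contrast depends on scaling. Listed ribosomal protein genes were higher in both heat tables, 12 of 12 at 0.5 M and 5 of 5 at 2.5 M. This goes with an effect of 24 h of culture, so that explanation stays open. It goes with it only weakly, since the 5 lie in 1 stretch of the chromosome. The 12 had a median log2 fold of 1.30, of which 0.40 comes from the authors' scaling.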
